A study of Mus musculus with 12 samples.

How the data were processed

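Per the labels' protocols, RNA of the sorted osteoblasts and endothelial cells was extracted with a Pico Pure kit, amplified as cDNA with an SPIA system and labelled with biotin. The deposited table holds log2 expression values of 34760 probe sets on 12 arrays, ranging from 1.55 to 12.9, and per the submitters' processing notes they were made with affy. The version of affy, its background correction and its normalization are not given in the sources used here. Signal over background per probe set was not used here. The labels call the arrays of a group biological replicates, and the design text speaks of 6 to 10 samples. Whether an array pools several mice, or shares mice with another, is not given in the sources used here, so p-values measure the spread between these samples.

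Groups were taken from the sample titles, 3 arrays in each of 4 groups, and every column of the table matched 1 sample. The arrays were compared before averaging: 0 of 66 pairs held identical values, and the highest correlation of a pair was 0.97. Genes were named through the array's annotation table, in which 21640 probe sets have 1 gene symbol, 1321 have several and 11799 are not listed. Of those with 1 symbol, 21553 matched the current gene table by Entrez number and 0 symbols changed. Probe sets with several symbols or none named no gene. Of 19937 genes 954 had several probe sets, and the one with the highest mean over the 12 arrays was used. Probe sets of a gene disagreed in sign for 12 of 38 such genes called in the osteoblast comparison, 52 of 225 in the cell type comparison and 1 of 1 in the comparison of differences.

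A gene was tested if its value lay above the median of all probe sets on at least 3 of the 12 arrays, which kept 12430 genes (62.3%) and left out 7507. The tests used limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 1 mean per group over all 12 arrays, no replicate block and default eBayes settings (8 residual and 2.89 prior degrees of freedom). They are two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are 2 to the power of the log2 difference. Standard errors come from the spread shared by all 4 groups, although tumor-free osteoblasts varied more than the others. The 35 gene lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Of 11 lists called in the osteoblast comparison, 8 in the endothelial, 1 in the comparison of differences and 11 in the cell type comparison, 0, 0, 0 and 4 were called with an estimated correlation. The lists hold 377 genes, of which 37 are not analysed here, and 1 was matched by a synonym.

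The gene lists, the tests, the settings in the first sentence of the next paragraph and the rule for the genes named in the text were set before the data were examined. For each tumor comparison the rule takes up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold whose groups do not overlap, and 5 each way for the cell type comparison and, without the overlap rule, for the comparison of differences. It adds the 3 members with the smallest p from each list past the threshold, and 12 fixed genes, of which 9 were measured; Ly6a, Bglap and Spp1 are not analysed here. Genes known only by a clone or model number were passed over. Other members of lists, among them Il6, S100a9, Jag1, Nfatc1 and Herpud1, were named after their values were seen.

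The other settings tried were the replicate number as a block, quantile normalization, median centering, no filter and a filter at the 70th percentile, the mean over probe sets, an intensity trend with robust estimation, array quality weights, a 2-fold minimum, only the groups compared, an average over tumor-free and tumor-bearing mice, and leaving out each array in turn. Array weights per group, hematopoietic or immediate early marker means as a covariate, and leaving out tumor-free replicate 1, or replicates 2 and 3, of both cell types were chosen after seeing the data. Each covariate had a slope shared by both cell types. A value with it need not reflect how genes followed the covariate within either cell type. Without replicates 2 and 3 each tumor-free group holds 1 array. Errors in that fit come from the tumor-bearing arrays alone, while tumor-free osteoblasts varied more. Whether a gene or list passes there therefore takes no account of the tumor-free spread.

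The steps were tested on simulated data with 200 of 12430 genes changed. With each group's spread as observed, changes of 1 and 2 on the log2 scale were recovered for 62% and 90% of genes in the osteoblast comparison, 49% and 90% in the endothelial, 48% and 97% in the cell type comparison and 15% and 71% in the comparison of differences. In the osteoblast comparison 56 of 208 calls were false, against 11 of 154 with equal spread, since the unequal spread of the groups breaks the shared estimate. False calls were 0 of 139 in the endothelial comparison, 32 of 177 in the cell type comparison and 7 of 93 in the comparison of differences. Simulated genes varied independently of each other and were drawn once per setting. These shares therefore do not cover genes that move together, as those of several lists did here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.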

Results

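Gene expression was measured in osteoblasts, the bone-forming cells, and in endothelial cells, which line blood vessels, both sorted from the long bones of female NOD-SCID mice, an immunodeficient strain. Tumor-bearing mice had received 200000 MDA-MB-231 scp1833 cells, a line derived from human breast cancer, into the heart, and tumors grew in the long bones for about 2 weeks. Both cell types were sorted as cells without GFP, CD45 and the marker labelled TR119. Osteoblasts were those with CD51 and without SCA1 and CD31, and endothelial cells those with both SCA1 and CD31. The 12 arrays form 4 groups of 3 biological replicates: osteoblasts and endothelial cells, each from tumor-free and from tumor-bearing mice. Array medians lay between 5.21 and 5.41 (log2 expression). Replicates correlated at 0.867 to 0.908 in tumor-free osteoblasts and at 0.946 to 0.969 in the other groups. The median SD of a gene over 3 replicates was 0.328 in tumor-free osteoblasts, 0.219 in osteoblasts of tumor-bearing mice, 0.173 in tumor-free endothelial cells and 0.189 in endothelial cells of tumor-bearing mice, and the number of arrays limits the precision of each value below.

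The first comparison set endothelial cells against osteoblasts of tumor-free mice and so describes what the sort separated. Pecam1, which encodes the sort marker CD31, stood at 10.76 ± 0.08 in endothelial cells and 5.69 ± 0.61 in osteoblasts (log2, mean ± SD, n = 3 each), a 33.5-fold difference (log2 difference 5.07 ± 0.29 SE, adjusted p = 9.12e-07 by limma). Cdh5, the endothelial cadherin, was 47.8-fold higher (adjusted p = 4.27e-05) and Kdr, a receptor for vascular endothelial growth factor, 39.9-fold higher in endothelial cells (adjusted p = 2.81e-06). In the other direction Col1a1, a chain of type I collagen, was 10.1-fold higher in osteoblasts (adjusted p = 0.00297). Itgav, which encodes CD51, was 2.16-fold higher there (adjusted p = 0.012). Ptprc, which encodes CD45, differed by -1.70 ± 0.79 (SE), short of the threshold (adjusted p = 0.119), with -2.54 (adjusted p = 0.0207) and -0.77 (adjusted p = 0.376) without tumor-free osteoblast replicate 1 or 2. Col1a1 was 19.9-fold higher without tumor-free osteoblast replicate 1, and Cdh5 differed 77.6-fold without replicate 2. With tumor-free replicate 1 of each cell type alone (replicates 2 and 3 left out) Col1a1 differed 2.74-fold, and Itgav 1.12-fold and did not pass (adjusted p = 0.773), nor did Itgav without tumor-free endothelial replicate 3 (adjusted p = 0.05).

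Among genes past the threshold, Rasgrp3, Emcn, Cd36, Adgrl4 and Gimap4 had the largest differences toward endothelial cells, from 59.1-fold for Gimap4 to 74.5-fold for Rasgrp3. Lum, Dcn, Ibsp, Fap and Ccdc80 had the largest toward osteoblasts, from 28.2-fold for Ccdc80 to 75.3-fold for Lum, a collagen-binding proteoglycan. Fap differed 59.9-fold without tumor-free endothelial replicate 1 and 38.2-fold with it. With tumor-free replicate 1 of each cell type alone Fap differed 9.99-fold, and Cd36, Lum and Ccdc80 differed 135-fold, 124-fold and 55.3-fold. All 16 endothelial marker genes were higher in endothelial cells, with a list median of 3.50 (camera adjusted p = 3.41e-20, and adjusted p = 0.00186 with an estimated correlation). Of 9 osteoblast genes tested, 8 were lower in endothelial cells (median -3.58, adjusted p = 5.64e-08, and adjusted p = 0.0156 with an estimated correlation), among them Ibsp, Alpl and Phex. Of 11 extracellular matrix genes 9 were lower (median -2.39, adjusted p = 1.43e-08, and adjusted p = 0.0156 with an estimated correlation), and so were 6 of 6 fibroblast genes (median -1.62, adjusted p = 1.26e-05, and adjusted p = 0.0408 with an estimated correlation). Adjusted over the list alone, the counts were 16, 8, 10 and 6 for these 4 lists.

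Sinusoidal endothelial genes (5 of 9 higher, adjusted p = 0.000278, median 2.66) and arterial endothelial genes (7 of 11 higher and 2 lower, adjusted p = 0.00255) were higher in endothelial cells, with adjusted p = 0.248 and 0.229 with an estimated correlation. Chondrocyte genes were lower there (7 of 10, median -2.99, adjusted p = 0.000278), with adjusted p = 0.538 with an estimated correlation. Their median was -1.795 without tumor-free osteoblast replicate 1, whose list mean was 9.94 against 8.50 and 6.20 on replicates 2 and 3, it was -1.553 without tumor-free replicate 1 of both cell types and -5.198 against that replicate alone. Notch signaling genes were higher (8 of 12 higher and 1 lower, adjusted p = 0.0314) and Wnt signaling genes lower (5 of 9, adjusted p = 0.0314), with adjusted p = 0.355 and 0.518 with an estimated correlation. Notch1 was 4.16-fold higher and Sfrp4, a secreted Wnt antagonist, 9.75-fold lower (15.8-fold without tumor-free endothelial replicate 1, and 2.94-fold with adjusted p = 0.185 with tumor-free replicate 1 of each cell type alone). Markers of neutrophils (3 of 9 lower, adjusted p = 0.0137) and of monocytes and macrophages (6 of 11 lower and 1 higher, adjusted p = 0.0252) were lower in endothelial cells, with adjusted p = 0.538 and 0.707 with an estimated correlation. Cd14, a macrophage marker, was the exception and stood 3.13-fold higher in endothelial cells (adjusted p = 0.0789 with tumor-free replicate 1 alone). The 4 Notch, Wnt, neutrophil and macrophage calls ended when single osteoblast arrays were left out, with adjusted p up to 0.0805 for Notch (without tumor-free osteoblast replicate 1 or 2) and up to 0.0793, 0.0666 and 0.119 for Wnt, neutrophil and macrophage genes (without replicate 2 or 3). The neutrophil median of -1.49 was -2.576 without tumor-free osteoblast replicate 1 and -0.963 without replicate 2. With tumor-free replicate 1 of each cell type alone, neutrophil, macrophage and Wnt genes had medians of -0.074, -0.336 and -0.581 and did not pass (adjusted p = 0.732, 0.981 and 0.352), nor did Notch genes without that replicate (adjusted p = 0.111). With hematopoietic markers as a covariate the neutrophil, macrophage and Wnt calls ended too (adjusted p = 0.464, 0.386 and 0.128), as they did with no filter on dim genes (adjusted p = 0.0842, 0.179 and 0.141). The neutrophil and macrophage calls also ended with the immediate early covariate (adjusted p = 0.0561 and 0.0822), and the macrophage call after quantile normalization (adjusted p = 0.0558), while without tumor-free replicate 1 of both cell types these lists passed at medians of -2.752 and -4.255. The fibroblast list above passed with a smaller median of -0.662 with that replicate alone, -0.731 with hematopoietic markers as a covariate and -1.05 with no filter. Adjusted over the list alone, 5 sinusoidal and 8 arterial genes were higher with 2 arterial genes lower, 10 chondrocyte genes were lower, 8 Notch genes were higher and 3 lower, and 5 Wnt and 6 neutrophil genes were lower, as were 9 macrophage genes with 1 higher.

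By limma 3850 of 12430 genes differed between the cell types, 2266 higher and 1584 lower in endothelial cells, and 1937 of them differed by at least 2-fold. The groups did not overlap for 3712 of the 3850, and for 47.3% of all genes, where chance gives 10%. The count was 2534, 2266 and 2333 when tumor-free endothelial replicate 1, 2 or 3 was left out, 1911 with these 6 arrays alone, 6564 with no filter on dim genes, 2529 with weights per group and 2090 with tumor-free replicates 2 and 3 of both cell types left out. With arrays centred on their medians the calls were 2852 higher and 785 lower.

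The second comparison asked what differed in osteoblasts of tumor-bearing mice, and most of the genes past the threshold were higher there. F3, which encodes tissue factor, the initiator of blood coagulation, rose from 6.10 ± 2.03 to 10.25 ± 0.40 (log2, mean ± SD, n = 3 each), a 17.8-fold difference (log2 difference 4.15 ± 0.74 SE, adjusted p = 0.0133 by limma). Cytl1, which encodes a secreted protein of cartilage, rose 16.2-fold (adjusted p = 0.0131), and Chil1, a secreted chitinase-like protein, rose from 6.88 ± 0.92 to 9.90 ± 0.43 (8.12-fold, adjusted p = 0.00527). Arih2, a ubiquitin ligase, rose 8.96-fold (adjusted p = 0.0057), and Fmo2, Uck2, Tmbim1 and Anxa8 rose between 7.86-fold and 8.65-fold. Wfdc17, a secreted protein made by macrophages, fell 6.77-fold (adjusted p = 0.0366), and Slc16a9, a member of the monocarboxylate transporter family, fell 3.02-fold (adjusted p = 0.0126). Ftl1, the ferritin light chain, fell 2.33-fold (adjusted p = 0.02), and Snord49b, Dmac1, Snapc3, Kcnj8 and Nceh1 fell between 2.35-fold and 3.63-fold. The unused probe sets of Arih2, Uck2 and Slc16a9 gave smaller log2 differences of the same sign, 1.54, 1.69 and -0.18. Without tumor-free osteoblast replicate 1 the folds of F3, Cytl1, Uck2, Tmbim1, Anxa8 and Wfdc17 were 39.9, 30.5, 17.1, 15.0, 15.6 and 11.6, and without replicate 3 those of F3, Cytl1, Uck2 and Wfdc17 were 11.1, 8.82, 4.65 and 3.92. Against tumor-free replicate 1 alone (replicates 2 and 3 of both cell types left out) F3, Cytl1, Chil1 and Tmbim1 differed 3.51-fold, 4.55-fold, 3.90-fold and 2.65-fold and Arih2 14.9-fold. Fmo2 and Slc16a9 differed 12.3-fold and 2.60-fold there, and Uck2, Anxa8 and Wfdc17 2.03-fold, 2.00-fold and 2.33-fold. Snord49b, Dmac1, Snapc3, Kcnj8, Nceh1 and Ftl1 differed between 1.74-fold and 2.52-fold. That fit has 1 tumor-free array per cell type and so no measure of the tumor-free spread.

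**Figure D1:**
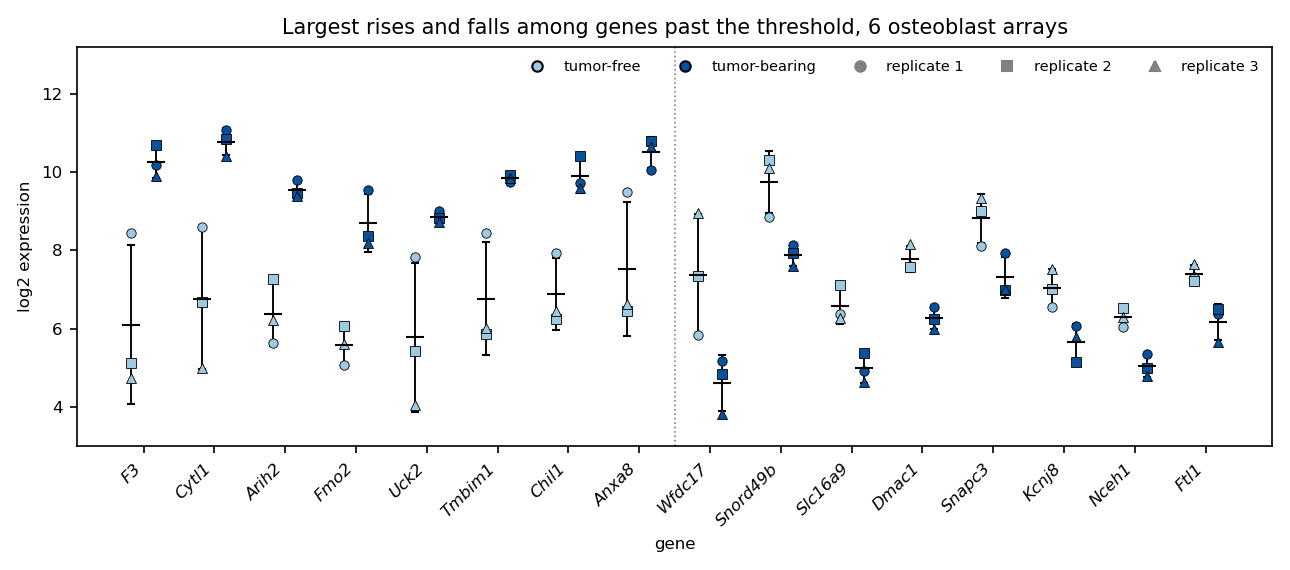
Log2 expression (vertical axis) of 16 genes (horizontal axis), the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, on the 6 osteoblast arrays, light points for tumor-free and dark points for tumor-bearing mice, with bars for the mean and SD of 3 arrays. For each gene the 3 arrays of one group lie on one side of the 3 of the other, and tumor-free replicate 1 stands nearest to the tumor-bearing arrays for F3 at a group SD of 2.03.

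Genes that regulate osteoclasts, the bone-resorbing cells, rose as a list (camera adjusted p = 0.00108, median 1.12). That call had adjusted p = 0.0993 with an estimated correlation. Of 9 members tested 3 rose over all genes and 6 adjusted over the list alone. Tnfrsf11b, which encodes osteoprotegerin, a decoy receptor for the osteoclast factor RANKL, rose from 6.04 ± 0.57 to 7.65 ± 0.53 (3.06-fold, adjusted p = 0.0148). Ptgs2, the inducible prostaglandin synthase, rose 6.71-fold (adjusted p = 0.0102) and Il11, a cytokine of the interleukin-6 family, 2.17-fold (adjusted p = 0.0133). Tnfsf11, which encodes RANKL itself, differed by 0.25 ± 0.24 (SE) and did not pass (adjusted p = 0.535). Inflammatory cytokine and adhesion genes, a list that shares Ptgs2 and Il6 with the former, also rose (adjusted p = 0.00248, median 0.96), with adjusted p = 0.443 with an estimated correlation. Of 15 members 3 rose over all genes and 6 adjusted over the list alone, with Lif at 4.51-fold (adjusted p = 0.0265) and the neutrophil chemokine Cxcl1 at 2.23-fold (adjusted p = 0.0478). Its median was 0.63 without tumor-free osteoblast replicate 3. With 1 array left out at a time, Il11 passed in 11 of 12 fits, Lif in 10 and Cxcl1 in 2. Ptgs2 passed against tumor-free replicate 1 alone (adjusted p = 0.0201), while Tnfrsf11b (1.97-fold), Il11, Lif and Cxcl1 did not (adjusted p = 0.0683 to 0.151).

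Hypoxia and glycolysis genes rose (adjusted p = 0.000164, median 0.68), with adjusted p = 0.191 with an estimated correlation, and 3 of 12 members passed over all genes, 5 adjusted over the list alone. Hk2, a hexokinase, rose 6.10-fold (adjusted p = 0.00757), Slc2a1, a glucose transporter, 4.39-fold (adjusted p = 0.0173) and Ldha, lactate dehydrogenase, 1.71-fold (adjusted p = 0.0295). Against tumor-free replicate 1 alone (replicates 2 and 3 of both cell types left out) that list had a median of 0.487 and did not pass (adjusted p = 0.0563). Smooth muscle and pericyte genes rose (adjusted p = 0.000827, median 1.30), with adjusted p = 0.369 with an estimated correlation. Acta2, Cnn1 and Tagln, which encode proteins of the contractile cytoskeleton, rose 6.75-fold, 4.01-fold and 2.81-fold, and 5 of the 8 members passed adjusted over the list alone. Targets of TGF-beta rose (adjusted p = 0.000827, median 1.03), with adjusted p = 0.0993 with an estimated correlation. Of its 10 members Ccn2 (2.94-fold, adjusted p = 0.0132) and Thbs1 (2.15-fold, adjusted p = 0.0343), both secreted matrix proteins, rose, and 6 passed adjusted over the list alone. Matrix proteases and their inhibitors rose (adjusted p = 0.0243, median 0.54), with adjusted p = 0.369 with an estimated correlation, through the protease inhibitor Timp3 (3.98-fold) and the protease Adamts1 (2.14-fold) among 10 members, and 3 passed adjusted over the list alone. That list did not pass without tumor-free osteoblast replicate 1 or tumor-bearing osteoblast replicate 1, with adjusted p up to 0.158. Its median was 0.306 without tumor-free replicate 1, 0.842 without tumor-free replicate 2 and 0.848 without tumor-bearing replicate 3 of the osteoblasts. It was 0.995 with hematopoietic markers as a covariate (adjusted p = 0.000972) and 0.991 against tumor-free replicate 1 alone (adjusted p = 0.00643), and the list did not pass without that replicate of both cell types (adjusted p = 0.109). With 1 array left out at a time, Hk2 passed in 12 of 12 fits, Slc2a1, Acta2 and Ccn2 in 11, Timp3 in 10, Ldha and Tagln in 9, Thbs1 in 6, Adamts1 in 5 and Cnn1 in 4. Against tumor-free replicate 1 alone Slc2a1 and Acta2 differed 2.91-fold and 6.60-fold, and Hk2, Ccn2 and Timp3 3.58-fold, 1.93-fold and 1.89-fold. Ldha, Tagln, Cnn1, Thbs1 and Adamts1 differed 1.49-fold, 2.12-fold, 3.31-fold, 1.91-fold and 1.76-fold there.

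Immediate early genes, which respond within minutes to stimulation and also to tissue dissociation, rose (adjusted p = 8.37e-05, median 1.02), with adjusted p = 0.389 with an estimated correlation. Nr4a1 (3.09-fold, adjusted p = 0.00942) and Fosb (2.48-fold, adjusted p = 0.0415) passed over all genes, and 7 of 11 members passed adjusted over the list alone. The mean of this list was 9.24, 8.64 and 8.13 on tumor-free osteoblast replicates 1, 2 and 3, and 9.69, 9.73 and 9.62 on the tumor-bearing ones. With that mean as a covariate 5 of the 570 genes called in this comparison remained past the threshold. The 499 higher genes had a median difference of 1.02 (median SE 0.334) with it and 1.27 (median SE 0.238) without it, the 71 lower genes -0.64 (0.236) and -0.71 (0.154), and all 570 kept their sign, so the calls ended through smaller differences with larger errors. Of the 11 lists called here, osteoclast regulators passed with it (median 0.692, adjusted p = 0.0481). None of the 10 others did, and among them the medians were 0.07 for immediate early, 0.155 for inflammatory, 0.365 for hypoxia, 0.584 for TGF-beta, 0.67 for chondrocyte, 0.681 for smooth muscle and 0.851 for matrix protease genes (adjusted p = 0.0896 to 0.941 for these 7). Against tumor-free replicate 1 alone the immediate early median was 0.365 (adjusted p = 0.0411). Nr4a1 passed in 12 and Fosb in 4 of the 12 fits with 1 array left out.

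Chondrocyte genes, which mark cartilage, rose in osteoblasts of tumor-bearing mice (adjusted p = 0.000341, median 1.97), with adjusted p = 0.443 with an estimated correlation. Col2a1, the main cartilage collagen, rose from 8.27 ± 0.64 to 10.19 ± 0.70 (3.79-fold, adjusted p = 0.0194), the 1 member of 10 past the threshold over all genes, and 4 passed adjusted over the list alone. Sox9, the transcription factor of cartilage, stood at 8.01 ± 1.48 and 10.03 ± 0.25 (adjusted p = 0.0604, and 0.000147 without tumor-free osteoblast replicate 1). The mean of this list was 9.94, 8.50 and 6.20 on tumor-free replicates 1, 2 and 3, and 9.68, 10.54 and 10.51 on the tumor-bearing ones. Its median was 0.978 without tumor-free osteoblast replicate 3, and against tumor-free replicate 1 alone it was 0.216 (adjusted p = 0.593). Col2a1 passed in 10 of the 12 fits with 1 array left out and did not against that replicate alone (adjusted p = 0.118).

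Markers of monocytes and macrophages were lower as a list (adjusted p = 0.0458, median -1.05), with adjusted p = 0.758 with an estimated correlation and 0 of 11 members past the limma threshold over all genes or adjusted over the list alone. Their mean was 5.32, 8.97 and 8.73 on tumor-free osteoblast replicates 1, 2 and 3 and 7.55, 7.12 and 5.21 on the tumor-bearing ones. Ptprc stood at 4.92, 8.46 and 6.41 and at 7.03, 6.88 and 4.70 on the same arrays. The list did not pass when any of 6 arrays was left out (tumor-free osteoblast replicate 2 or 3, tumor-bearing osteoblast replicate 3, tumor-free endothelial replicate 1, tumor-bearing endothelial replicate 2 or 3), with adjusted p up to 0.455. Its median was -2.532 and -0.514 without tumor-free osteoblast replicate 1 or 2, and -1.625 and -0.699 without tumor-bearing osteoblast replicate 1 or 3. It turned to 1.285 against tumor-free replicate 1 alone, to 0.361 with the immediate early covariate and to 0.04 with hematopoietic markers as a covariate (adjusted p = 0.126, 0.958 and 0.821), and the list did not pass after quantile normalization or with no filter (adjusted p = 0.107 and 0.25). Markers of the B lineage were lower (adjusted p = 0.0243, median -0.48), with adjusted p = 0.389 with an estimated correlation. Cd79b, part of the B-cell receptor, and Vpreb3 fell 1.96-fold and 1.49-fold, 2 of 4 members both over all genes and adjusted over the list alone. Vpreb3 stood at 5.01 to 5.81 on the osteoblast arrays, near the array medians of 5.28 to 5.41. With 1 array left out at a time, Cd79b passed in 7 of 12 fits and Vpreb3 in 0, and neither did against tumor-free replicate 1 alone (adjusted p = 0.244 and 0.117). Without tumor-free replicate 2 or tumor-bearing replicate 1 of the osteoblasts that list did not pass, with adjusted p up to 0.0835, nor did it after quantile normalization, with the immediate early covariate or against tumor-free replicate 1 alone (adjusted p = 0.0582, 0.129 and 0.126). Endothelial markers were lower (adjusted p = 0.00232, median -0.44), with adjusted p = 0.191 with an estimated correlation and none of 16 members past the threshold over all genes or adjusted over the list alone (Flt1 differed by -0.54 ± 0.15 SE, adjusted p = 0.0611). Their median was -0.253 without tumor-free osteoblast replicate 2 and -0.23 against tumor-free replicate 1 alone, and the list did not pass with the immediate early covariate (median -0.265, adjusted p = 0.213). On the osteoblast arrays Flt1, Tek and Emcn stood at 3.74 to 5.55, mostly near or below the array medians of 5.28 to 5.41, while Egfl7 stood above them at 6.02 to 6.79. The lower list value thus includes genes at low signal in osteoblasts.

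The osteoblast markers did not pass as a list (adjusted p = 0.864), with a median of -0.0042 that lay above 0 after quantile normalization (0.0131) and median centering (0.053). Col1a1 differed by -0.20 ± 0.61 (SE, adjusted p = 0.869), which turned to 1.746 against tumor-free replicate 1 alone (adjusted p = 0.0122) and was -1.168 without that osteoblast array (adjusted p = 0.00495), and Ibsp by -0.02 ± 0.36 (adjusted p = 0.985). Cell cycle genes had a median of -0.03 (adjusted p = 0.771), which was 0.028 with median centering, and neutrophil markers one of -1.31 (adjusted p = 0.0524).

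**Figure D2:**
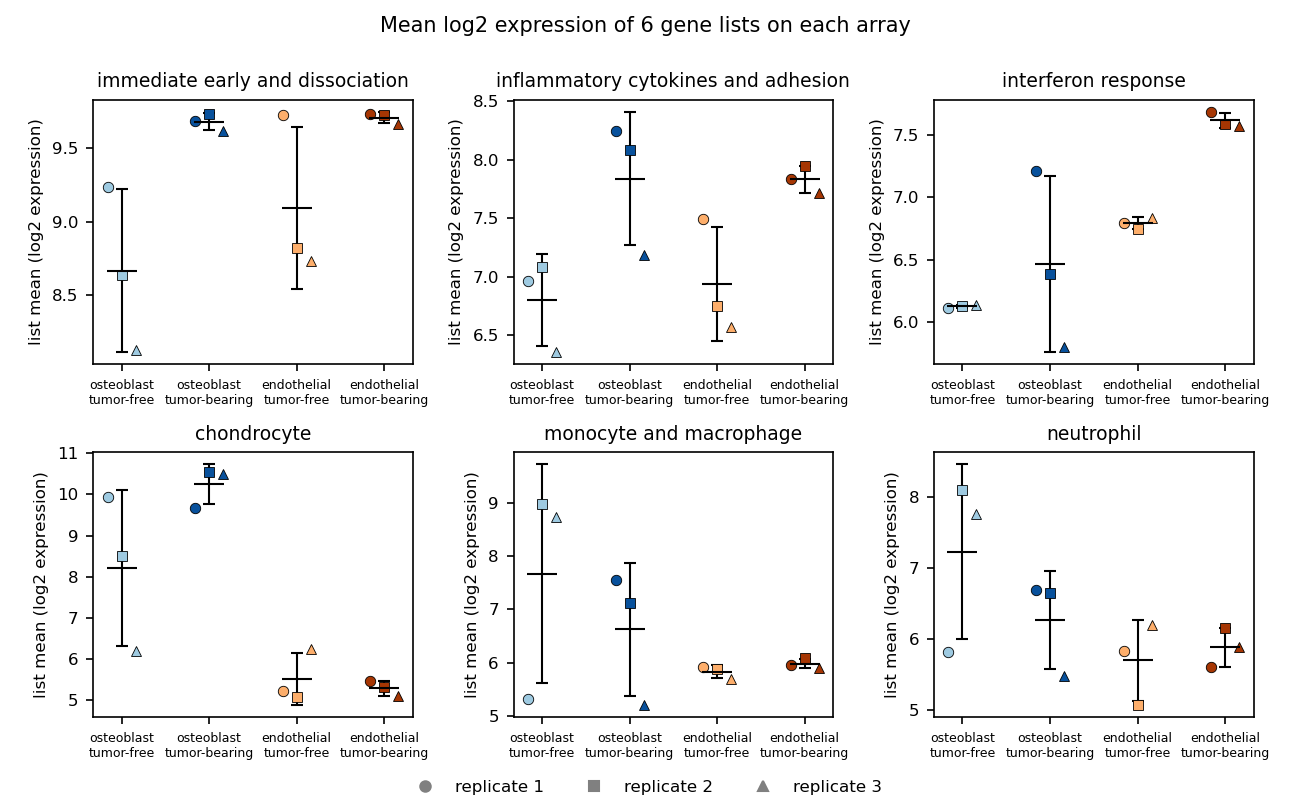
Mean log2 expression (vertical axes) of the tested genes of 6 lists on each of the 12 arrays in 4 groups (horizontal axes), with a symbol per replicate and bars for the mean and SD of 3 arrays. Interferon response genes separate the endothelial groups (6.80, 6.75 and 6.84 against 7.68, 7.58 and 7.57), while macrophage markers range from 5.32 to 8.97 within tumor-free osteoblasts.

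By limma 570 of 12430 genes differed between osteoblasts of tumor-bearing and tumor-free mice, 499 higher and 71 lower, and 374 of them differed by at least 2-fold. The split was 368 higher and 184 lower after quantile normalization and 551 higher and 404 lower with no filter on dim genes. The groups did not overlap for 568 of the 570, and for 24.7% of all genes, where chance gives 10%. Without tumor-free osteoblast replicate 1, 2 or 3 the count was 1573, 878 or 364, without tumor-bearing replicate 1, 2 or 3 it was 318, 111 or 376, without tumor-free endothelial replicate 2 or 3 it was 349 or 347, and without endothelial replicate 1 or 2 of tumor-bearing mice 310 or 357. It was 0 with the 6 osteoblast arrays alone (1820 genes at an unadjusted p under 0.05), 955 with no filter on dim genes, 130 with weights per group, 910 with hematopoietic markers as a covariate, 1421 without tumor-free replicate 1 and 905 without tumor-free replicates 2 and 3 of both cell types. With 1 array left out at a time, Arih2, Chil1 and Slc16a9 passed in all 12 fits, F3, Cytl1, Tmbim1, Kcnj8, Ftl1, Tnfrsf11b and Ptgs2 in 11, Fmo2 in 10, Dmac1 in 9, Anxa8 in 7, Nceh1 in 4, Snapc3 in 3, Snord49b in 2, and Uck2 and Wfdc17 in 1.

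The third comparison put the same question to endothelial cells, where 3 genes passed. Abcb1b, which encodes a P-glycoprotein drug efflux pump, rose from 4.06 ± 0.28 to 6.15 ± 0.15 (log2, mean ± SD, n = 3 each), a 4.26-fold difference (log2 difference 2.09 ± 0.27 SE, adjusted p = 0.0458 by limma). Stxbp6, a syntaxin-binding protein, rose from 5.67 ± 0.31 to 7.45 ± 0.20 (3.43-fold, adjusted p = 0.0458). Lpar6, a receptor for lysophosphatidic acid, fell from 9.86 ± 0.19 to 8.49 ± 0.02 (2.60-fold, adjusted p = 0.0458). The sort and vessel genes Pecam1, Cdh5 and Kdr differed by 0.05 ± 0.29, -0.06 ± 0.54 and -0.38 ± 0.36 (SE), none past the threshold.

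Interferon response genes rose as a list in endothelial cells (camera adjusted p = 6.98e-07, median 0.62), with adjusted p = 0.397 with an estimated correlation. All 11 members had positive differences, 0 passed limma's threshold over all genes and 1 passed adjusted over the list alone. That member, Mx2, an antiviral GTPase, stood at 4.37 ± 0.21 and 6.74 ± 0.34 (5.19-fold, adjusted p = 0.0597 over all genes). Inflammatory cytokine and adhesion genes rose (adjusted p = 6.98e-07, median 0.77), with adjusted p = 0.397 with an estimated correlation. None of its 15 members passed over all genes and 7 passed adjusted over the list alone, among them the chemokines Ccl2 (5.70-fold, unadjusted p = 0.00518 by limma) and Cxcl2 (5.32-fold, unadjusted p = 0.00534). Cxcl2 stood at 7.98, 5.86 and 5.44 on tumor-free replicates 1, 2 and 3 and differed 9.12-fold without tumor-free endothelial replicate 1, and against tumor-free replicate 1 alone Ccl2 and Cxcl2 differed 2.72-fold and 1.82-fold. The mean of this list was 7.49, 6.75 and 6.57 on tumor-free replicates 1, 2 and 3, and 7.84, 7.95 and 7.72 on the tumor-bearing ones. Its median was 0.327 against tumor-free replicate 1 alone (replicates 2 and 3 of both cell types left out), where the list did not pass (adjusted p = 0.178), and 0.401 with the immediate early mean as a covariate (adjusted p = 0.00595).

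Immediate early genes rose in endothelial cells too (adjusted p = 6.98e-07, median 0.54), with adjusted p = 0.397 with an estimated correlation. None of 11 members passed over all genes or adjusted over the list alone, and Egr1 and Dusp1 differed by 0.64 ± 0.24 and 0.79 ± 0.30 (SE). Their mean was 9.73, 8.82 and 8.73 on tumor-free replicates 1, 2 and 3, and 9.73, 9.73 and 9.66 on the tumor-bearing ones. That list's median was 0.86 without tumor-free endothelial replicate 1, 0.321 without tumor-free endothelial replicate 3 and 0.004 against tumor-free replicate 1 alone (adjusted p = 0.921), and 0.092 with its own mean as a covariate (adjusted p = 0.816). Genes of CXCL12-abundant reticular stroma, a marrow cell type that holds blood stem cells, rose (adjusted p = 7.98e-05, median 0.68), with adjusted p = 0.397 with an estimated correlation. None of its 10 members passed over all genes or adjusted over the list alone, and Lepr and Adipoq differed by 1.29 ± 0.45 and 1.34 ± 0.49 (SE). Lepr stood at 8.42, 7.18 and 6.96 on tumor-free replicates 1, 2 and 3 and at 8.79, 8.87 and 8.78 on the tumor-bearing ones. Adipoq differed by 0.70 without tumor-free endothelial replicate 3. Against tumor-free replicate 1 alone Lepr and Adipoq differed by 0.39 and 0.32, and the list had a median of 0.31. With the immediate early covariate the list passed (median 0.847, camera adjusted p = 0.0016). The slope of that covariate is shared with osteoblasts, where Lepr ran the other way (8.57, 9.46 and 9.62 on tumor-free replicates 1, 2 and 3). The larger median therefore does not bear on handling in endothelial cells. Smooth muscle and pericyte genes rose (adjusted p = 0.00148, median 0.45), with adjusted p = 0.397 with an estimated correlation, and 1 of 8 members, Tagln (2.41-fold), passed adjusted over the list alone. They did not pass against tumor-free replicate 1 alone (median 0.082, adjusted p = 0.624) or with the immediate early covariate (median 0.361, adjusted p = 0.214).

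Hypoxia and glycolysis genes (adjusted p = 0.0105, median 0.23, Ankrd37 at 1.88-fold) and hematopoietic niche factors (adjusted p = 0.0119, median 0.56, Angpt1 at 2.39-fold) rose, with adjusted p = 0.397 and 0.417 with an estimated correlation and no member past the threshold over all genes or adjusted over the list alone. The niche list shares Cxcl12, Kitl, Angpt1 and Il7 with the reticular stroma list above, so those calls are not independent. Hypoxia genes did not pass without tumor-free or tumor-bearing endothelial replicate 3 (adjusted p up to 0.107), nor did niche factors without tumor-bearing endothelial replicate 3 (adjusted p = 0.0516). The hypoxia median was 0.347 and 0.345 without tumor-free or tumor-bearing endothelial replicate 1. With the immediate early covariate it was 0.13 (camera adjusted p = 0.594), while the niche factors passed at a median of 0.704 (camera adjusted p = 0.0034). The covariate's shared slope limits the latter value too. Against tumor-free replicate 1 alone neither list passed (medians 0.156 and 0.163, adjusted p = 0.624 for both). Angpt1 stood at 5.37, 4.17 and 4.18 on tumor-free replicates 1, 2 and 3 and at 6.03, 5.90 and 5.56 on the tumor-bearing ones, 1.38-fold against tumor-free replicate 1 alone. Endothelial markers fell as a list (adjusted p = 0.00737, median -0.26), with adjusted p = 0.397 with an estimated correlation, and Robo4, a vessel guidance receptor, was 1.46-fold lower, 1 of 16 members adjusted over the list alone and none over all genes. They did not pass against tumor-free replicate 1 alone (median -0.185, adjusted p = 0.588) or with the immediate early covariate (median -0.194, adjusted p = 0.234).

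The 3 genes were of 12430 tested by limma, with 861 at an unadjusted p under 0.05, and the groups did not overlap for 18.8% of all genes, where chance gives 10%. The count was 61 without tumor-free endothelial replicate 1, 1 without tumor-free osteoblast replicate 3, 2 without tumor-bearing osteoblast replicate 1 and 0 without any of the other 9 arrays (468 to 1170 genes at an unadjusted p under 0.05). It was 449 with array quality weights, 38 with weights per group, 159 without tumor-free replicate 1 of both cell types, 7 with probe sets averaged, 6 with hematopoietic markers as a covariate, and 0 under the quantile, median, unfiltered, stricter-filter, trend, immediate early and tumor-free replicate 2 and 3 settings (436 to 1186 genes at an unadjusted p under 0.05). With 1 array left out at a time, Abcb1b and Lpar6 passed in 2 of 12 fits and Stxbp6 in 1. Fry called 0 of the 35 lists in this comparison.

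The fourth comparison tested whether the tumor-associated difference itself differed between the cell types. Kera, a proteoglycan known as keratocan, had a log2 difference of 2.60 ± 0.31 (SE) in osteoblasts and -0.14 ± 0.31 in endothelial cells, a gap of 2.73 ± 0.44 (adjusted p = 0.0413 by limma). Lbp, which binds bacterial lipopolysaccharide, had 2.05 ± 0.22 and -0.23 ± 0.22 (gap 2.28, adjusted p = 0.0279), and Slc41a1, a magnesium transporter, 2.45 ± 0.22 and 0.09 ± 0.22 (gap 2.37, adjusted p = 0.0279). Mtmr12 and Abhd2 had gaps of 2.44 and 2.59 in the same direction. Abcb1b had -0.39 ± 0.27 in osteoblasts and 2.09 ± 0.27 in endothelial cells (gap -2.48, adjusted p = 0.0329), and Ablim3, an actin-binding protein, Stxbp6 and Acr, the sperm protease acrosin, had gaps of -2.23, -2.11 and -1.29. Kera stood at 3.29 to 3.57 on the endothelial arrays, and Abcb1b and Ablim3 at 3.81 to 5.05 on the osteoblast arrays, below the array medians of 5.21 to 5.41. The gaps of these genes set a difference in a single cell type against low signal in the other. Lbp, Slc41a1, Mtmr12, Abhd2 and Stxbp6 stood above the array medians in both cell types.

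Chondrocyte genes had larger differences in osteoblasts than in endothelial cells as a list (camera adjusted p = 0.00438, median gap 2.08), with adjusted p = 0.8 with an estimated correlation. None of its 10 members passed over all genes and 1, Col2a1 (gap 1.94 ± 0.52 SE), passed adjusted over the list alone. Without tumor-free osteoblast replicate 3 that list had a median of 1.338 (adjusted p = 0.0694), against tumor-free replicate 1 alone 0.101 (adjusted p = 0.878), and with the hematopoietic or the immediate early covariate 1.516 and 1.763 (adjusted p = 0.072 and 0.077). Interferon response genes had a median gap of -0.46 and did not pass (adjusted p = 0.0824), so their rise in endothelial cells was not shown to differ from the osteoblast median of 0.53. Tnfrsf11b had a gap of 1.52 ± 0.42 (adjusted p = 0.149) and Ptgs2 one of 2.86 ± 0.63 (adjusted p = 0.0828), both short of the threshold.

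By limma 26 of 12430 genes differed in this way, 22 with the larger value in osteoblasts and 4 in endothelial cells, with 1990 at an unadjusted p under 0.05. The count was 545, 223 and 40 without tumor-free osteoblast replicate 1, 2 or 3, 13 without tumor-bearing osteoblast replicate 3 and 0 without tumor-bearing osteoblast replicate 2, tumor-free endothelial replicate 2 or 3, or any tumor-bearing endothelial array (1472 to 1948 at an unadjusted p under 0.05). It was 324 with array quality weights, 96 with median centering, 112 with hematopoietic markers and 15 with immediate early genes as a covariate, 378 without tumor-free replicate 1 and 96 without tumor-free replicates 2 and 3 of both cell types, 41 with probe sets averaged, 14 after quantile normalization and 11 with the stricter filter. With 1 array left out at a time, Mtmr12, Slc41a1 and Lbp passed in 6 of 12 fits, Abhd2, Abcb1b, Ablim3 and Stxbp6 in 4, Kera in 3 and Acr in 2. Abhd2, Mtmr12 and Lbp passed against tumor-free replicate 1 alone, and the other 6 did not (adjusted p = 0.0506 to 0.141).

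The last comparison set the log2 differences of both cell types beside each other across genes, which are not independent replicates. Over 12430 genes Pearson's r was 0.126 and Spearman's rho 0.01. No gene past the threshold was shared (0 of 499 and 2 higher genes, where independent lists share 0.0803, and 0 of 71 and 1 lower genes, where they share 0.00571). At an unadjusted limma p under 0.05, 129 genes were higher in both cell types where independent lists share 59.4 (odds ratio 2.85), and 47 were lower in both where they share 44.8 (odds ratio 1.06). Fmo2, a flavin monooxygenase, was among the former, with 8.65-fold in osteoblasts and 5.76-fold in endothelial cells (unadjusted p = 0.00121). Its tumor-free endothelial arrays stood at 9.30, 7.32 and 6.65 and the tumor-bearing ones at 10.38, 10.21 and 10.25, so that the endothelial fold was 9.82 without tumor-free endothelial replicate 1 and 1.98 against tumor-free replicate 1 alone. Of the 570 osteoblast genes 314 had the same sign in endothelial cells, 55.1% against 47.3% of all genes. The value of r was 0.171 without tumor-free replicate 1 of both cell types and turned to -0.028 without tumor-free replicates 2 and 3, and it was 0.069 with no filter and 0.299 with immediate early genes as a covariate. Leaving out tumor-free osteoblast replicate 2 or tumor-free endothelial replicate 2 gave 0.084 or 0.081.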

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

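Of the tests below, those of shared quality, of handling in the immediate early, interferon and inflammatory lists and of cartilage cells, as well as the settings with a covariate and without tumor-free replicates, were chosen only after the values they bear on had been seen.

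The tumor-associated difference differed between osteoblasts and endothelial cells for 26 genes. Kera, Abhd2, Mtmr12, Slc41a1 and Lbp had gaps of 2.73, 2.59, 2.44, 2.37 and 2.28 (log2, osteoblast minus endothelial difference). Abcb1b, Ablim3, Stxbp6 and Acr had gaps of -2.48, -2.23, -2.11 and -1.29. Kera had low signal in endothelial cells, and Abcb1b and Ablim3 in osteoblasts. The chondrocyte list had a median gap of 2.08, with camera adjusted p = 0.8 with an estimated correlation. Its median gap was 0.101 against tumor-free replicate 1 alone. When tumor labels were reassigned within each cell type, 3 of 100 drawn assignments (of 200 distinct ones, the real one included) gave at least 26 genes. Such reassignment removes the tumor difference from both cell types and does not keep an equal difference in both. It therefore cannot exclude chance for a gap between them. Of the 26 genes, 0 passed in all 12 fits with 1 array left out. The highest other assignment gave 165 genes, several times the real count, which points to a structure of the samples whose cause was not tested.

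Probe sets that name no gene here also passed limma's threshold, 96 of 5461 in the osteoblast comparison, 11 in the comparison of differences and 438 in the cell type comparison.

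For the comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave the largest count, with 570 genes against 197 for the highest other split in osteoblasts, 3 against 1 in endothelial cells and 3850 against 1 for cell type. The osteoblast split with 197 genes set tumor-free replicate 1 with tumor-bearing replicates 2 and 3. The correlation between cell types was as large in 9 of 100 reassignments, the highest other being 0.256, so chance cannot be excluded for r = 0.126.

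The 499 genes higher in osteoblasts of tumor-bearing mice had a median log2 difference of 1.27, between 1.18 and 1.30 with 1 array left out. Their median was 1.23 with the mean of 9 neutrophil and 11 macrophage markers as a covariate. Hematopoietic cells in the tumor-free sorts, which the CD45 gate is meant to remove, are not excluded by this. Called genes have a small spread within groups relative to their difference, while these markers varied widely within tumor-free osteoblasts. Genes that follow the markers would thus be called less readily. Wfdc17, made by macrophages, was called lower even so, at 5.84, 7.34 and 8.96 on tumor-free osteoblast replicates 1, 2 and 3. The 71 lower genes had a median of -0.719 with the covariate and -0.705 without it, which is open to the same limit. S100a9 stood at 10.15 ± 0.89 and 8.72 ± 1.09, and C1qb at 7.33 ± 1.93 and 5.66 ± 0.73, in tumor-free and tumor-bearing osteoblasts. Genes called higher without tumor-free replicate 1, 2 or 3 shifted on the array left out by only 0.375, 0.5 or 0.943 of the fitted median, a ratio that the selection of called genes also lowers. Losses in amplification that differ between tumor-free arrays would lower it and stay possible. The ratio measures only how those arrays differ from each other, so it cannot name amplification as the source. A quality difference shared by the tumor-free arrays cannot be told apart from the tumor, because the interquartile range of genes not called was higher on each tumor-bearing than on each tumor-free osteoblast array, by at least 0.0261 (log2). The presence of the tumor stays open as the biological explanation, and no test here isolates it.

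Immediate early, interferon and inflammatory genes rose as lists in endothelial cells, each with camera adjusted p = 0.397 with an estimated correlation. Immediate early genes were lowest on tumor-free replicates 2 and 3 of both cell types. Handling that set those arrays apart cannot be told apart from the tumor for the immediate early list, since tumor-free replicate 1 lay 0.659 of the way from them to the tumor-bearing arrays in osteoblasts and 1.02 in endothelial cells, values that prompted the explanation. For the interferon list handling of replicates 2 and 3 is argued against. Its mean was 6.80, 6.75 and 6.84 on tumor-free endothelial replicates 1, 2 and 3, and 7.68, 7.58 and 7.57 on the tumor-bearing ones. Its median was 0.62 (0.503 to 0.78 with 1 array left out), 0.766 against tumor-free replicate 1 alone and 0.66 with the immediate early mean as a covariate, whose slope is shared with osteoblasts. Handling that set all tumor-free endothelial arrays apart cannot be told apart from the tumor. For the inflammatory list handling may contribute and cannot be told apart, since its median was 0.401 with that covariate and 0.765 without, and 0.327 against tumor-free replicate 1 alone (camera adjusted p = 0.178). An interferon response to the tumor remains a hypothesis, with adjusted p = 0.397 for the list with an estimated correlation.

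Chondrocyte genes rose in osteoblasts of tumor-bearing mice with a median of 1.97 (camera adjusted p = 0.443 with an estimated correlation). The median was 0.216 against tumor-free replicate 1 alone. A candidate explanation is a differing share of cartilage cells, for which the sort has no marker. The 10 genes of the list, all of them above the filter in these arrays, moved together within groups, with a median pair correlation of 0.885 where random genes of like level reach 0.255 at the 95th percentile. Comp and Col2a1, 2 of its abundant genes, stood at 9.40 ± 1.23 and 8.27 ± 0.64 in tumor-free and at 11.16 ± 0.29 and 10.19 ± 0.70 in tumor-bearing osteoblasts. A changed share and a change within the cells cannot be told apart, because genes of 1 program would also move together and the correlation was tested on arrays already seen.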

How the results depend on the processing

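The array weights per group, both covariates and the settings without tumor-free replicates were chosen only after the results were seen, and the other settings were planned. Where no cause is named, the cause was not tested.

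With the replicate block the osteoblast count was 349, the endothelial and interaction counts 0 (854 and 1861 genes at an unadjusted limma p under 0.05) and the lists called in the interaction 2. The numbers were not shown to pair the samples: same-numbered arrays correlated at -0.26 to 0.11 and in 7 of 18 comparisons the best match had its own number. Between the 2 cell types these correlations were 0.095, 0.074 and -0.0028 in tumor-free and 0.002, 0.071 and -0.046 in tumor-bearing mice. Shared mice or a shared sort day cannot be excluded by this, since many of the comparisons set tumor-bearing against tumor-free mice.

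The osteoblast count (570) was 955 with no filter, 374 with a 2-fold minimum, 0 with only its 2 groups (fewer arrays, 1820 unadjusted), 130 with weights per group, 910 with the hematopoietic and 5 with the immediate early covariate, 1421 without tumor-free replicate 1 and 905 without tumor-free replicates 2 and 3. The endothelial count (3) was 0 after quantile normalization, median centering, no filter, the 70th percentile filter, the trend, the immediate early covariate and without tumor-free replicates 2 and 3, 7 with averaged probe sets, 449 with quality weights, 38 with weights per group, 6 with the hematopoietic covariate and 159 without tumor-free replicate 1. The interaction count (26) was 14, 96, 11, 41 and 324 for quantile, median centering, 70th percentile, averaged probe sets and quality weights, 112 and 15 with the hematopoietic and immediate early covariates, 378 without tumor-free replicate 1 and 96 without tumor-free replicates 2 and 3. The cell type count (3850) was 6564 with no filter, 1911 with only its 2 groups, 1937 with a 2-fold minimum, 2529 with weights per group and 2090 without tumor-free replicates 2 and 3.

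With each array left out in turn the osteoblast count ran from 111 to 1573, the endothelial from 0 to 61, the interaction from 0 to 545, the cell type count from 2266 to 3921 and r from 0.081 to 0.167. Of the calls, 100 of 570 (17.5%), 0 of 3, 0 of 26 and 1876 of 3850 (48.7%) remained in all 12 fits. Lists called ran from 9 to 15, 6 to 12, 0 to 6 and 7 to 13. For the interaction they were 6 without tumor-free or tumor-bearing osteoblast replicate 1, 5 without tumor-bearing osteoblast replicate 2 or 3 or tumor-free endothelial replicate 3, 2 without tumor-bearing endothelial replicate 2 and 0 without tumor-free osteoblast replicate 3, and for cell type 7 without tumor-free osteoblast replicate 2.

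Higher against lower calls moved from 499 and 71 in osteoblasts to 368 and 184 after quantile normalization and to 551 and 404 with no filter, and for cell type from 2266 and 1584 to 2852 and 785 after median centering and 2422 and 4142 with no filter. Median centering put the median of all genes at 0.149 for the interaction and 0.181 for cell type, and no called list turned its sign under a scaling.

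The correlation r (0.126) was 0.069 with no filter, 0.091 and 0.299 with the hematopoietic and immediate early covariates, 0.171 without tumor-free replicate 1 and -0.028 without tumor-free replicates 2 and 3. Lists called in osteoblasts (11) were 17 with no filter, 1 with the immediate early covariate and 0 with an estimated correlation. Fry called 11 there too, without the chondrocyte, inflammatory and macrophage lists (fry adjusted p = 0.0719, 0.0704 and 0.43). In their place it called extracellular matrix, skeletal muscle and T and NK genes (fry adjusted p = 0.0306, 0.0343 and 0.0042). In endothelial cells (8) they were 14 without tumor-free replicate 1, 1 without tumor-free replicates 2 and 3, 0 with an estimated correlation and 0 by fry. In the interaction (1) they were 8 with no filter, 6 with weights per group, 0 with the immediate early covariate, 5 without tumor-free replicate 1, 2 without replicates 2 and 3, 0 with an estimated correlation and 3 by fry. For cell type (11) they were 4 with an estimated correlation and 12 by fry, which left out neutrophil and macrophage genes (fry adjusted p = 0.0692 and 0.138). The 3 interaction lists called by fry were osteoclast regulators, T and NK genes and TGF-beta targets (fry adjusted p = 0.0229, 0.0229 and 0.0377). The chondrocyte list did not pass by fry in the interaction (fry adjusted p = 0.326).

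These values reversed: the osteoblast macrophage median (-1.05) was 0.04 with the hematopoietic covariate, built from those genes, and 1.285 without tumor-free replicates 2 and 3, and its median, not its test, turned to 0.361 with the immediate early covariate. With that covariate the endothelial macrophage median (-0.005) was 1.033 and passed. The slope is shared with osteoblasts, whose tumor-free list means ranged from 5.32 to 8.97, while those of the endothelial arrays lay between 5.705 and 6.085. The value of 1.033 therefore does not show a rise of these markers in endothelial cells. Without tumor-free replicates 2 and 3 the cell type macrophage test turned at a median of -0.336, the endothelial immediate early test at 0.004 and Col1a1 in osteoblasts to 1.746. In that setting the lone array is assumed to vary like the other groups. The osteoblast immediate early test turned at 0.07 with its own mean as the covariate. Values past the threshold in neither fit turned sign too, for 7 of 56 named genes in osteoblasts (Ptprc, Cdh5 and Pecam1 among them), 7 of 36 in endothelial cells, 8 of 21 in the interaction and 1 of 49 in the cell type comparison, and for 15, 15, 22 and 11 of 35 list medians. Calls of named genes were lost, with the adjusted p no longer under 0.05, in 285 osteoblast, 56 endothelial, 97 interaction and 77 cell type fits. Signal over background was not used here, so what it limits was not assessed.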

Other observations

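The lists and genes below were tested as planned, and none was added after the results were seen except the single genes named from them and 1 setting, which is named as such.

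Extracellular matrix genes went both ways in osteoblasts of tumor-bearing mice. As a list they did not pass by camera (adjusted p = 0.0663, median 0.24) and passed by fry (adjusted p = 0.0306). Of 11 members 4 rose over all genes by limma and 5 adjusted over the list alone. Fn1, which encodes fibronectin, rose 2.16-fold (adjusted p = 0.0294), Bgn, a small proteoglycan, 1.84-fold (adjusted p = 0.032), and Col12a1 and Col6a1, both collagen chains, 1.68-fold and 2.02-fold (adjusted p = 0.0316 and 0.0489). Postn and Tnc, matrix proteins of remodelling tissue, differed by -0.22 ± 0.57 and -0.39 ± 0.73 (SE). Among other lists that did not pass, Jag1, a Notch ligand, rose 2.55-fold in osteoblasts (adjusted p = 0.0426), Nfatc1, a transcription factor of osteoclasts, 3.01-fold (adjusted p = 0.0375) and Herpud1, a gene of the unfolded protein response, 2.98-fold (adjusted p = 0.044). Against tumor-free replicate 1 alone (replicates 2 and 3 of both cell types left out, chosen after the data were seen) Jag1 differed 4.24-fold (adjusted p = 0.0241) and Nfatc1 1.52-fold (adjusted p = 0.268).

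Interferon response genes varied among the osteoblast arrays of tumor-bearing mice, with list means of 7.21, 6.38 and 5.81 on replicates 1, 2 and 3, while the tumor-free osteoblast arrays stood at 6.12, 6.14 and 6.14. Antigen presentation genes had negative gaps for 9 of 9 members between the osteoblast and endothelial differences (median -0.76) and did not pass (camera adjusted p = 0.0639). Ribosomal protein genes had medians of 0.09 in osteoblasts and -0.09 in endothelial cells and passed in neither (adjusted p = 0.348 and 0.211).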
